A study of Mus musculus with 6 samples.

How the data were processed

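Total RNA from the skin of 3 WT and 3 LynDN transgenic mice was extracted with Qiagen reagents, labelled with Ambion reagents and hybridised to 2-colour arrays, per the labels' protocols. The 6 arrays form 3 dye swaps, each of the same 2 mice, with channel 1 in Cy3 and channel 2 in Cy5 on every array, per the labels. The scanner, the background correction and the normalization within arrays are not given in the sources used here. The deposited table gives 1 log2 ratio per probe and array, where the authors' log base is not stated and base 2 was assumed, since the range of values is too wide for base 10. Each deposited column had a mean of 0, with medians from -0.02 to 0.00. Neither the numerator nor the method of centring is stated. From row 21000 on, 98.6% of rows carry at most 3 significant digits on all arrays, and S100a9 lies among the rows of this part. Whether these rows differ from the others in more than rounding was not tested. Spot intensities were not used here, so no signal could be set against its background, and saturation of bright spots could not be examined. Dye bias was visible in rows named for reference genes: the mean over 257 Gapdh rows lay between -0.12 and 0.06 on arrays with LynDN in Cy3 and between 0.28 and 0.47 on those with LynDN in Cy5. The mean over 305 Actb rows lay between -0.04 and 0.17 on the 6 arrays.

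Rows were named through the platform annotation. Of 25344 probes, 21082 had 1 gene symbol, 30 had several and 4232 had no entry. An Entrez identifier was found in a RefSeq gene table of GRCm38.p6 for 20456 probes, and 0 symbols changed. Probes with exactly 1 symbol were averaged per symbol on each array, and all others stayed as unnamed rows. Some genes keep older names, such as Lor for loricrin and Il1f6 for Il36a.

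The 2 arrays of a dye swap hold the same RNAs and were averaged, so that a dye effect cancels, which left 3 pair values per row. The labels give the same 2 mice on both arrays of a pair, and this is where the pairing comes from. The mean of the 3 pair values was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over 22879 rows and a threshold of 0.05. The fit had a prior of 2.96 degrees of freedom. An alternative fit took the 6 arrays with a dye term and the mouse pair as a random block (duplicateCorrelation, consensus correlation 0.151). Its single correlation for all rows leaves out that some genes vary more between pairs than others. Mice are named as separate animals in the labels, so the spread between pairs is biological and technical together. SDs are over the 3 pair values, each a mean of 2 arrays. They leave out differences between the 2 arrays of a dye swap, so a small SD does not show that the arrays agreed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

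Gene lists were fixed before the data were examined, 31 in number, covering Lyn, keratins, barrier and antimicrobial genes, cytokines, chemokines, signalling pathways and markers of skin and blood cell types. Lists with at least 4 measured genes, 29 of them, were tested with camera at a preset inter-gene correlation of 0.01 on the 3 pair values, adjusted over lists, and again with the correlation estimated per list and with fry. Members were also tested adjusted over the list alone. This adjustment leaves out the number of lists, so passing it is weaker than passing over all rows. Genes named in the text were chosen by a rule fixed at the same time. It took Lyn, then up to 12 genes per side with the largest ratio among those past the threshold with the same sign on 6 arrays, and then up to 4 members of each list with the smallest p. Where fewer than 5 genes passed on a side, it also took the 8 with the smallest p there, as values. Other members of the lists were named after their values were seen: Slpi, Defb14, Lcn2, Tgm3, Tgm1, Krt10, Il18, Vcam1 and Retnlg.

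The test was checked on simulated data: 22879 rows over 3 mouse pairs with 200 changed rows in each of 20 runs. With the spread of changed rows drawn from the fitted prior, 91.8% of rows changed 2-fold, 98.5% of those changed 4-fold and 99.9% of those changed 16-fold were recovered, and 5.45% of calls were unchanged rows. With the spread that the real rows of at least 2-fold show between pairs, recovery was 13.1%, 37.1% and 73.0%. The block fit, in 5 runs on the same kind of simulated rows, recovered 9.85%, 37.9% and 82.4%, with 5.68% of calls on unchanged rows. All simulated rows shared 1 correlation between the arrays of a pair, as the block fit assumes. Its rate of false calls on real rows that vary mostly between pairs was therefore not tested. In a simulated list test camera found 1 list shifted by 0.5 and called 0 of 28 unshifted lists. Rows were drawn independently of one another there, in 1 run. The check therefore cannot show how the preset correlation fares on lists whose genes vary together, such as the wound cornified envelope (estimated correlation 0.549).

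Alternatives fixed before the data were examined were the block fit, arrays as independent, median, scale and quantile normalization between arrays, robust and no variance moderation, other thresholds, every probe as a row, a missing-value rule, each dye orientation alone, and each mouse pair left out in turn. No chromosome positions are given, since no genome of the array design's build was used here.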

Results

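Skin of 3 wild-type (WT) mice and of 3 mice carrying the LynDN transgene was compared on 2-colour oligonucleotide arrays. Lyn is a Src family tyrosine kinase, and the series title writes the transgene as LynDeltaN. Each of 3 mouse pairs was hybridised on 2 arrays with the dyes exchanged, which gave 6 arrays. Pair 1 joined LynDN mouse 1 and WT mouse 1, pair 2 joined LynDN mouse 2 and WT mouse 3, and pair 3 joined LynDN mouse 3 and WT mouse 2. The deposited table held a log ratio for 25344 probes on every array, from -6.34 to 6.16, with no missing value. After averaging probes of one gene, 22879 rows were tested, of which 18617 were named genes and 4262 were unnamed probes. The number of arrays limits the precision, and the mouse pair was the unit of replication in the test reported first (n = 3), while alternative fits used the 6 arrays.

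The sign of a ratio is given here as deposited, because the numerator is not stated. Within dye swaps the deposited ratios correlated positively across rows in pairs 2 and 3 (Pearson r = 0.463 and 0.462) and at 0.0239 in pair 1, where genes are not independent replicates. The rank correlations were 0.127 and 0.155 in pairs 2 and 3 and -0.180 in pair 1. The alarmin genes S100a9 and S100a8 were positive on all 6 arrays, and 121 of the 137 rows with a mean ratio of at least 2-fold had one sign on all 6 arrays. These rows were picked by the mean of the same arrays, which partly fixes their agreement in sign. In pair 1 the correlation over all rows does not show a shared direction. Of 230 rows picked without pair 1, by a mean of at least 2-fold in pairs 2 and 3, 208 had the same sign in pair 1. The Y-linked gene Eif2s3y gave 3.38 and 3.62 on the 2 arrays of pair 1. A shared direction in pair 1 thus shows in strongly differing rows. The values were used as deposited on all arrays. Which genotype is the numerator stays open: if WT were the numerator, every sign given here would turn at once. A rule fixed before the data were examined called a direction likely only if Lyn itself lay on one side in all pairs, and no probe was named Lyn (0 probes). Mice of this kind are known for an inflamed, psoriasis-like skin, which would put LynDN in the numerator, but with Lyn not analysed here positive and negative mark opposite sides only. The log base is not stated either, and folds assume base 2.

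The comparison of genotypes asked which genes differ in skin. Among genes that passed the test, the largest difference was that of the calcium-binding alarmins S100a9, with a mean log2 ratio of 5.54 ± 0.16 (SD, n = 3), and S100a8, with 4.61 ± 0.12 (SD, n = 3), which correspond to 46.4-fold and 24.4-fold. Krt16, a keratin of wounded and hyperproliferative epidermis, had a mean log2 ratio of 2.49 ± 0.16 (SD, n = 3), and Ccl20, a chemokine that attracts CCR6-bearing cells, had 2.13 ± 0.11 (SD, n = 3). These 4 genes passed the limma test, with adjusted p = 0.000149 for both alarmins and 0.00311 for Krt16 and Ccl20, and all 4 were positive on 6 of 6 arrays. On the negative side 0 genes passed in limma, where the smallest adjusted p was 0.112, while 1354 positive and 1466 negative rows had an unadjusted p under 0.05. At least 2-fold mean ratios were reached by 119 positive and 18 negative rows.

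The count of calls depended on how the pairs were treated. With the mouse pair as a random block over the 6 arrays, 243 rows passed, 138 positive and 105 negative, including the 4 genes above. That fit gives all rows 1 correlation, 0.151, between the arrays of a pair. For rows that vary mostly between pairs it treats dye swaps nearly as separate mice. Its false calls on such rows were not tested, so passes with the block are weaker than passes on the pair values. Without pair 1 the count was 1117, with 736 positive and 381 negative, and without pair 2 it was 2. Quantile normalization between arrays gave 72, of which 53 were positive and 19 negative. Without variance moderation, 0 rows passed.

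The next genes by p on the positive side are given as values, since they did not pass on the pair values. They were Sprr2a1 with 2.48 ± 0.41 (SD, n = 3; adjusted p = 0.0926), Chil1 with 1.33 ± 0.22, the beta-defensin Defb6 with 2.79 ± 0.54 and Sprr2d with 3.75 ± 0.76. Adjusted p was 0.112 for Chil1 and Defb6 and 0.116 for Sprr2d. On the negative side the smallest p belonged to the serine protease inhibitor Serpina3b, at -1.76 ± 0.32 (SD, n = 3; adjusted p = 0.112). Cfap57 had -1.31 ± 0.29, the esterase Ces2f had -0.80 ± 0.16, the tight junction gene Cldn23 had -0.76 ± 0.09 and the transporter Slc46a2 had -0.70 ± 0.09. Dkkl1, the catalase gene Cat and Itm2a had -0.68 ± 0.08, -0.68 ± 0.09 and -0.57 ± 0.06. For Dkkl1 the 2 arrays of pair 3 gave -0.04 and -1.22, a difference that the SD over pairs does not show. Each of the genes from Cfap57 to Itm2a had an adjusted p of 0.123 and was negative on 6 of 6 arrays. With the pair as a block, 11 of the 12 genes from Sprr2a1 to Itm2a passed, with adjusted p from 0.00137 for Sprr2a1 to 0.0198 for Slc46a2, and Dkkl1 did not (adjusted p = 0.0535). With every probe as a row of its own, 1 Cfap57 probe passed with a log2 ratio of -1.94 (adjusted p = 0.0251).

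**Figure D1:**
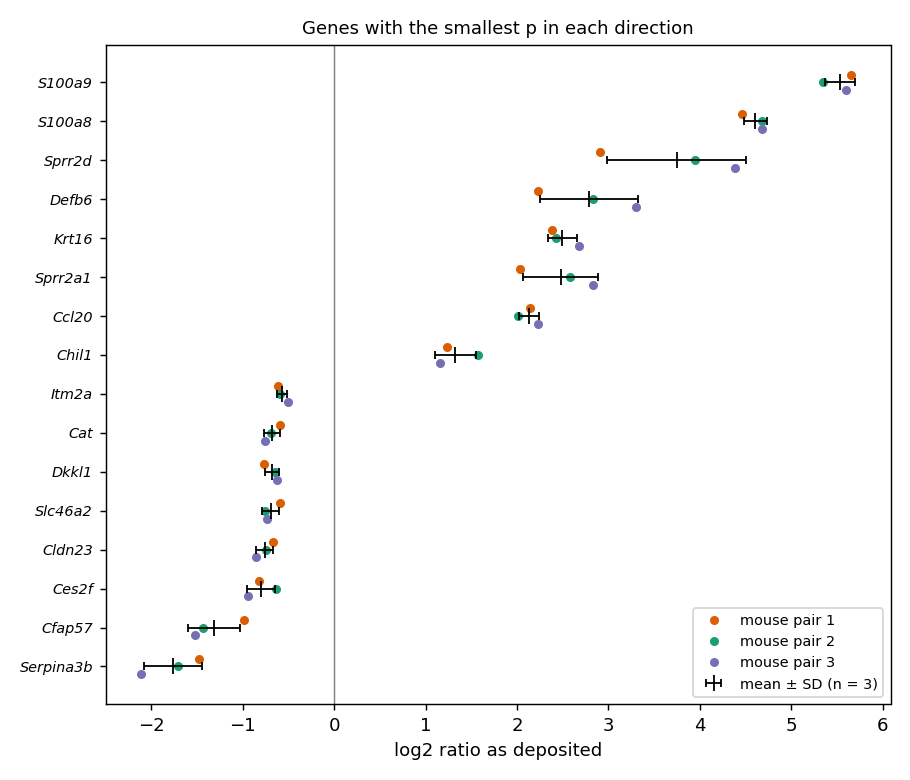
Log2 ratios as deposited (horizontal axis) of the 8 genes with the smallest p on each side, with a point for each of 3 mouse pairs and a bar for mean ± SD (n = 3). S100a9 and S100a8 lie farthest to the right, with means of 5.54 and 4.61, and Serpina3b farthest to the left, at -1.76.

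Agreement between the mouse pairs was uneven. Across rows, the ratios of pairs 2 and 3 correlated with r = 0.745, while pair 1 correlated with pair 2 at 0.350 and with pair 3 at 0.386. Pair 1 also had the smallest array SDs, with 0.258 and 0.274 against 0.333 to 0.360 in the other pairs. The interquartile ranges overlapped, with 0.238 and 0.256 in pair 1 against 0.248 to 0.274, so the bulk of the ratios differed less in width. Of the called genes, S100a9 had 5.65, 5.35 and 5.61 and Ccl20 had 2.14, 2.01 and 2.23 in pairs 1, 2 and 3, where a small spread between pairs is part of what the test selects. Sex-linked genes set pair 1 apart as well. The Y-linked genes Eif2s3y and Kdm5d had log2 ratios of 3.50 and 1.24 in pair 1 and lay between -0.05 and 0.13 in the other pairs, and Xist, which is expressed from the inactive X chromosome, had -1.06 in pair 1 against -0.09 and -0.14. Uty, also Y-linked, did not follow this, with 0.07, 0.13 and -0.48 in pairs 1, 2 and 3. The sex-linked list as a whole was not called by camera (4 genes, adjusted p = 0.730). That test could not show the difference in pair 1. The list joins Xist with Y-linked genes, which lie on opposite sides, and the test covers all pairs together.

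Wound cornified envelope genes, stress keratins and antimicrobial proteins had the highest list medians. Of 16 measured genes of the wound cornified envelope, cross-linked proteins and serpins of stressed epidermis, 15 were positive, and the median log2 ratio was 2.93 (1.46, 3.72 and 3.53 in pairs 1, 2 and 3). Adjusted over the list alone, 14 passed, all positive, among them Sprr1b with 3.68 ± 0.85 and Sprr2b with 3.42 ± 0.81 (SD, n = 3). With the pair as a block, 13 passed over all rows. Sprr1b had 2.92 and 2.53 on the arrays of pair 1, 4.22 and 3.67 in pair 2, and 4.68 and 4.07 in pair 3. Its spread thus lay mostly between pairs, where passes with the block are less certain. Apart from S100a9, S100a8, Krt16 and Ccl20, no list member passed over all rows on the pair values. Of 22 antimicrobial proteins and alarmins 17 passed adjusted over the list alone, all positive, with a median of 1.01 (0.55, 1.25 and 0.99 by pair). Besides the S100 genes, Chil1 and the stefin gene Stfa3, with 1.34 ± 0.26, led this list, and 10 members passed over all rows with the block. For Stfa3 the 2 arrays of pair 1 gave 0.28 and 1.8. Slpi, a protease inhibitor, had 3.06 ± 1.33, Defb14 had 3.12 ± 1.65 and the siderophore-binding Lcn2 had 1.88 ± 1.27. Camera called both lists with its preset correlation (adjusted p = 6.3e-20 for antimicrobial proteins and 3.57e-18 for the envelope), but neither with an estimated correlation (adjusted p = 0.467 for each with an estimated correlation). All 3 measured stress keratins (median 2.49) passed adjusted over the list alone: Krt16, Krt6b with 4.82 ± 1.21 and Krt17 with 0.60 ± 0.24 (SD, n = 3). Krt17 did not pass over all rows with the block (adjusted p = 0.0776). The stress keratin list was too short for camera. Sprr2, stefin and Krt6 genes are close paralogs whose probes can cross-hybridise, so single members are less certain than the family.

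Terminal differentiation genes were divided. Of 36 measured genes, 8 passed positive and 14 negative, adjusted over the list alone. Over all rows, 1 positive and 4 negative members passed with the block, and 0 on the pair values. Rptn, a filaggrin-type protein of the cornified layer, had 4.95 ± 1.28 (SD, n = 3), and the transglutaminases Tgm3 and Tgm1 had 0.93 ± 0.55 and 0.76 ± 0.59. In contrast, filaggrin itself (Flg) had -2.23 ± 0.86, loricrin (Lor) -1.67 ± 0.45, Lce1m -2.56 ± 0.80 and the suprabasal keratin Krt10 -1.77 ± 1.24. The list was not called (median -0.05, adjusted p = 0.154), and its medians were -0.22, 0.05 and 0.01 in pairs 1, 2 and 3. It was called negative without pair 2 (median -0.19, adjusted p = 0.000446) and without pair 3 (median -0.08, adjusted p = 0.0237) at the preset correlation, while the median was 0.034 without pair 1. Over all 3 pairs adjusted p = 0.683 with an estimated correlation, and members lay on both sides of 0 in this list. Basal keratinocyte genes had a median of 0.23 (0.15, 0.22 and 0.29 by pair), and 8 of 14 passed adjusted over the list alone, all positive. They included the keratin Krt14 with 1.34 ± 0.54, the hemidesmosome integrin genes Itgb4 and Itga6 with 0.47 ± 0.17 and 0.58 ± 0.35, and the transcription factor gene Trp63 with 0.32 ± 0.03 (SD, n = 3). For Trp63 the 2 arrays of pair 3 gave 0.65 and 0.02. Over all rows with the block, 2 basal keratinocyte genes passed, and Itga6 and Trp63 did not (adjusted p = 0.0747 and 0.112). The list was called with the preset correlation (adjusted p = 6.36e-08) and lost the call with an estimated one (adjusted p = 0.467 with an estimated correlation).

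**Figure D2:**
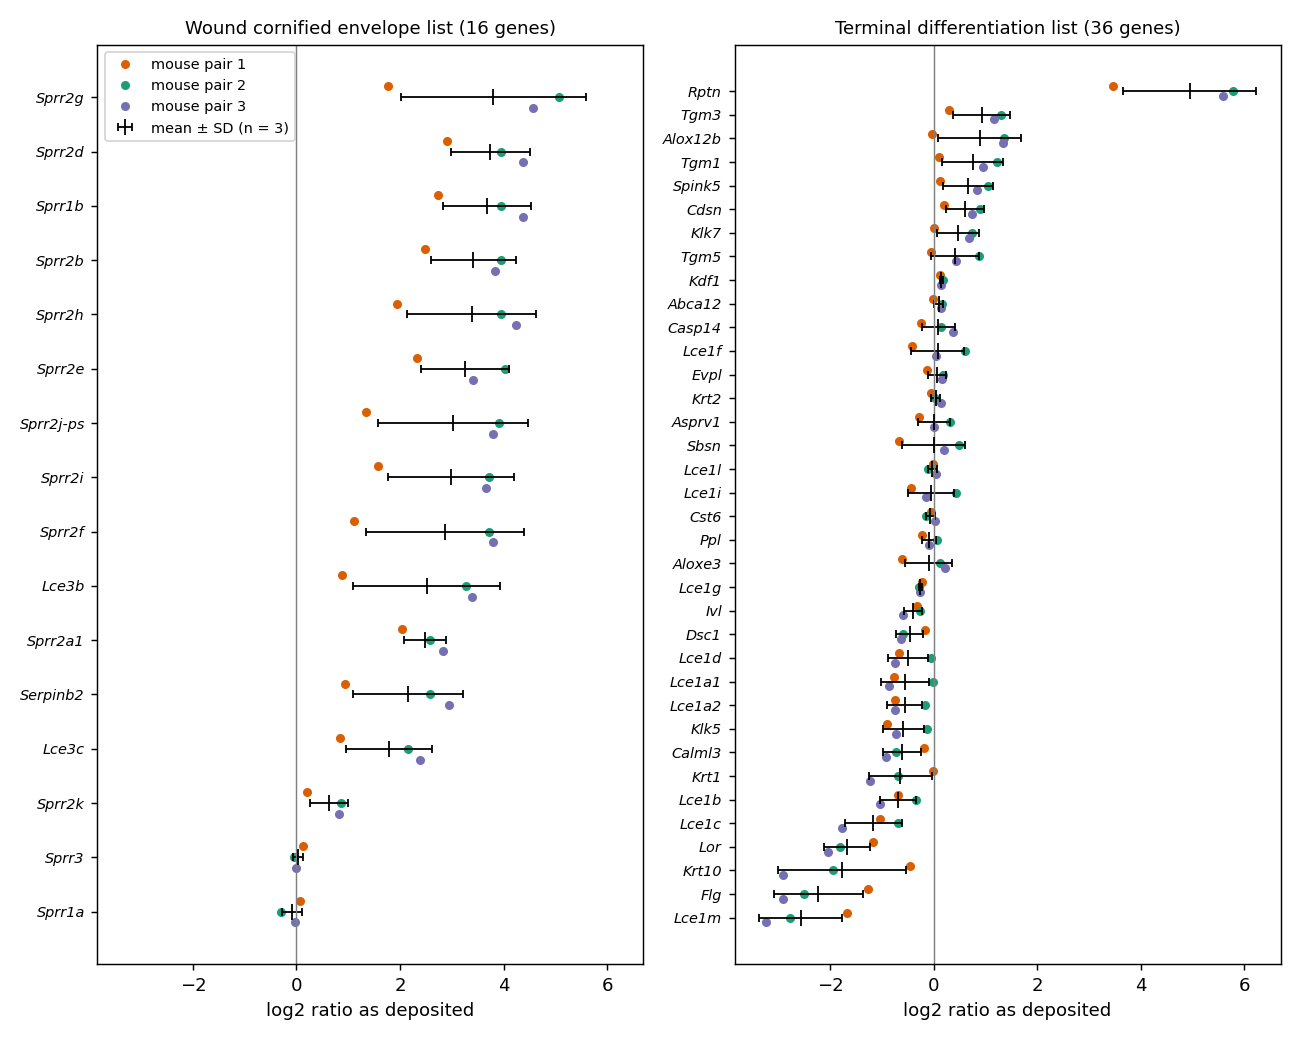
Log2 ratios as deposited (horizontal axes) of the 16 measured wound cornified envelope genes and the 36 measured terminal differentiation genes, with a point for each of 3 mouse pairs and a bar for mean ± SD (n = 3). Of the envelope genes 15 have a positive mean, while terminal differentiation genes range from Rptn at 4.95 to Lce1m at -2.56.

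Of the EGFR and cytokine genes that passed adjusted over their list alone, most were positive. Of 10 EGFR ligands and receptors, 4 passed positive and 1 negative, adjusted over the list alone: the ligands Epgn, Ereg and Hbegf had 1.68 ± 0.66, 1.28 ± 0.56 and 1.17 ± 0.66 (SD, n = 3), whereas the ligand Btc had -0.84 ± 0.33. Of 31 cytokines, 15 passed positive and 1 negative in the same sense. The IL-36 genes Il1f6 (Il36a), Il1f9 (Il36g) and Il1f8 (Il36b) had 2.77 ± 0.68, 1.84 ± 0.86 and 1.16 ± 0.49, the alarmin cytokine Il33 had 2.63 ± 1.32, and Il18 had -0.38 ± 0.18 as the negative one. Over all rows with the block, 6 cytokines passed positive and 0 negative, and 3 EGFR genes positive and 1 negative. The cytokine median was 0.30 (0.10, 0.44 and 0.43 by pair) and that of the EGFR list 0.10 (0.08, 0.21 and 0.06). Camera called both (adjusted p = 7.47e-11 and 0.0081) and neither with an estimated correlation (adjusted p = 0.467 for each with an estimated correlation).

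Chemokines and NF-kB targets were positive in most members. Of 29 chemokines 7 passed positive and 1 negative, adjusted over the list alone. Beside Ccl20, Cxcl14 had 0.47 ± 0.13 and the neutrophil attractant Cxcl1 0.72 ± 0.38, while Ccl27a, a chemokine made by keratinocytes, had -1.11 ± 0.62 (SD, n = 3). Of 24 NF-kB targets 7 passed positive and 1 negative: the regulators Zc3h12a, Nfkbiz and Bcl3 had 1.65 ± 0.62, 1.58 ± 0.64 and 1.02 ± 0.50, Tnfaip2 had 0.89 ± 0.31, and Vcam1, an adhesion molecule, had -0.26 ± 0.08. Of 18 STAT3 pathway genes 5 passed, all positive, such as Jak2 with 0.35 ± 0.13 and Socs3, a feedback inhibitor, with 0.83 ± 0.49. Over all rows with the block, 3 chemokines passed positive and 1 negative, and 5 NF-kB targets positive and 0 negative. Of the STAT3 genes 1 passed with the block, and Socs3 did not (adjusted p = 0.0663). The list medians in pairs 1, 2 and 3 were -0.01, 0.29 and 0.39 for chemokines, 0.02, 0.35 and 0.47 for NF-kB targets, and 0.03, 0.28 and 0.25 for the STAT3 pathway. All 3 lists were called with the preset correlation (adjusted p = 1.08e-06, 2.62e-07 and 5.9e-06) and none with an estimated one (adjusted p = 0.467 for each with an estimated correlation).

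Macrophage and monocyte markers had a median of 0.41, made up of -0.08 in pair 1, the pair set apart by sex-linked genes, and 0.53 and 0.84 in pairs 2 and 3. Of 23 members 0 passed positive and 1 negative, adjusted over the list alone. Lgals3, which keratinocytes also express, had -0.37 ± 0.09 (SD, n = 3), though the 2 arrays of pair 2 gave 0.01 and -0.75. The Fc receptor gene Fcgr3 and Cd53 each had 0.65, with SDs of 0.62 and 0.61. Neutrophil markers had medians of -0.02, 0.46 and 0.35 by pair, and 5 of 17 passed, all positive, including Csf3r with 0.38 ± 0.12, Cxcr2 with 0.55 ± 0.31 and Retnlg with 2.48 ± 1.80. Over all rows with the block, 1 neutrophil marker and 0 macrophage and monocyte markers passed, and Cxcr2 did not (adjusted p = 0.0622). Camera called the macrophage and the neutrophil list (adjusted p = 2.62e-07 and 3.61e-06), with adjusted p = 0.467 for each with an estimated correlation. Dendritic and Langerhans cell markers (14 genes, median 0.13) were called at adjusted p = 0.00631, without a member passing, and the MHC class II gene H2-Ab1 had 0.45 ± 0.31; with an estimated correlation adjusted p = 0.467. Mast cell markers (11 genes, median 0.09) were called at adjusted p = 0.0358, and adjusted p = 0.522 with an estimated correlation. T cell markers (20 genes, median 0.00, adjusted p = 0.872) and B cell markers (9 genes, median -0.02, adjusted p = 0.730) were not called.

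Interferon-stimulated genes (24 genes) were called positive at a median of 0.08 (adjusted p = 0.00777, and adjusted p = 0.683 with an estimated correlation), yet their median was -0.17 in pair 1 against 0.16 and 0.31 in pairs 2 and 3, and no member passed. Oas2 had 0.23 ± 0.27 (SD, n = 3). Tissue remodelling proteases (17 genes, median 0.06) were called at adjusted p = 0.0316, and adjusted p = 0.467 with an estimated correlation, with Plau, the urokinase gene, at 0.52 ± 0.37 and Adam8 at 1.03 ± 0.85. Leaving out pair 2 or pair 3 ended the calls of interferon-stimulated genes (adjusted p = 0.103 and 0.790), mast cell markers (0.201 and 0.166) and proteases (0.0800 and 0.239).

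Hair follicle genes were negative in most members, 37 of the 44 measured. Of these genes, 11 passed negative and 0 positive, adjusted over the list alone, and 9 passed negative over all rows with the block. The bulge and outer root sheath keratin Krt15 had -1.36 ± 0.33 and Krt23 had -0.54 ± 0.05 (SD, n = 3). The keratin-associated protein genes Krtap3-3 and Krtap4-7 had -0.52 ± 0.13 and -0.42 ± 0.10. Krt23 and Krtap3-3 depended on the dye orientation, which their SDs do not show. In pair 1 the arrays with LynDN in Cy3 and in Cy5 gave -0.31 and -0.78 for Krt23, and -0.05 and -0.87 for Krtap3-3. In pair 2 they gave -0.20 and -0.98, and -0.05 and -0.84. The list median was -0.41 (-0.03, -0.48 and -0.57 by pair), called at adjusted p = 7.58e-10 and lost at adjusted p = 0.467 with an estimated correlation. Fibroblast and extracellular matrix genes had a median of -0.11 (-0.15, -0.06 and -0.21 by pair). Of 30 members, 10 passed negative and 2 positive, adjusted over the list alone, among them the microfibril gene Mfap4 with -0.999 ± 0.41, Ogn with -0.58 ± 0.14 and fibronectin (Fn1) with -0.38 ± 0.11. Over all rows with the block, 2 members passed negative and 0 positive. This list was called at adjusted p = 0.000452, and adjusted p = 0.467 with an estimated correlation.

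Markers of muscle, pigment and blood were negative in pairs 2 and 3. Skeletal muscle genes (26 genes) had medians of 0.00, -0.32 and -0.50 by pair, with Actn3 at -0.62 ± 0.33 and Myl1 at -0.55 ± 0.30. Melanocyte genes (11 genes) had 0.17, -0.64 and -0.51, with the melanosome gene Mlana at -0.45 ± 0.71. Erythrocyte genes (4 genes) had -0.04, -1.07 and -0.32, with the globin gene Hba-a1 at -0.70 ± 0.64 (SD, n = 3). No member of these lists passed adjusted over the list alone, and camera called them at adjusted p = 2.88e-05, 0.0148 and 0.0225. With an estimated correlation, adjusted p = 0.522, 0.615 and 0.522. The melanocyte call was lost without pair 2 (adjusted p = 0.264) or pair 3 (0.122), and the erythrocyte call without pair 2 (0.0596).

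Several tissue compartments gave no call. These were endothelial markers (19 genes, median 0.02, adjusted p = 0.0868), sebaceous gland and lipid synthesis (28 genes, median -0.03, adjusted p = 0.629) and adipocyte genes (21 genes, median -0.07, adjusted p = 0.520). Cell division genes (31 genes, median -0.03, adjusted p = 0.107), immediate early and heat shock genes (16 genes, median 0.08, adjusted p = 0.0629) and Src family kinases and partners (19 genes, median 0.01, adjusted p = 0.709) were not called either. Among lipid synthesis genes 3 passed positive and 3 negative, adjusted over the list alone, such as the sterol demethylase gene Cyp51 with 0.47 ± 0.17 and Dgat2, which makes triglycerides, with -0.41 ± 0.23 (SD, n = 3). Selp was the 1 endothelial gene that passed in this sense, with 0.31 ± 0.05, though the 2 arrays of pair 1 gave -0.28 and 0.93. Zfp36 and Hspb1 were the immediate early and heat shock genes that passed in this sense, with 0.43 ± 0.20 and -0.31 ± 0.10. Over all rows with the block, 0 members of the lipid synthesis, endothelial and immediate early lists passed. The immediate early list was called with the pair as a block (adjusted p = 0.0293) and without pair 2 (0.0353), and adipocyte and cell division genes were called without pair 1 (0.0142 and 0.0343), all at the preset correlation. Over all 3 pairs these lists had adjusted p = 0.467, 0.811 and 0.638 with an estimated correlation. The mean and median differed in sign for the sebaceous, Src family and T cell lists, all of them close to 0.

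In all, camera called 19 of 29 tested lists with the preset correlation, 14 positive and 5 negative. With a correlation estimated from the data it called 0, and fry, which tests whether a list moves on balance one way, also called 0. With 3 pair values both tests have few residual degrees of freedom, so a lost call need not come from the correlation itself. The adjusted p of immediate early and heat shock genes also rose, from 0.0629 to 0.467, at an estimated correlation of -0.025. Fry's test for change in either direction called 2, the antimicrobial proteins (adjusted p = 0.00283) and the chemokines (adjusted p = 0.0313).

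**Figure D3:**
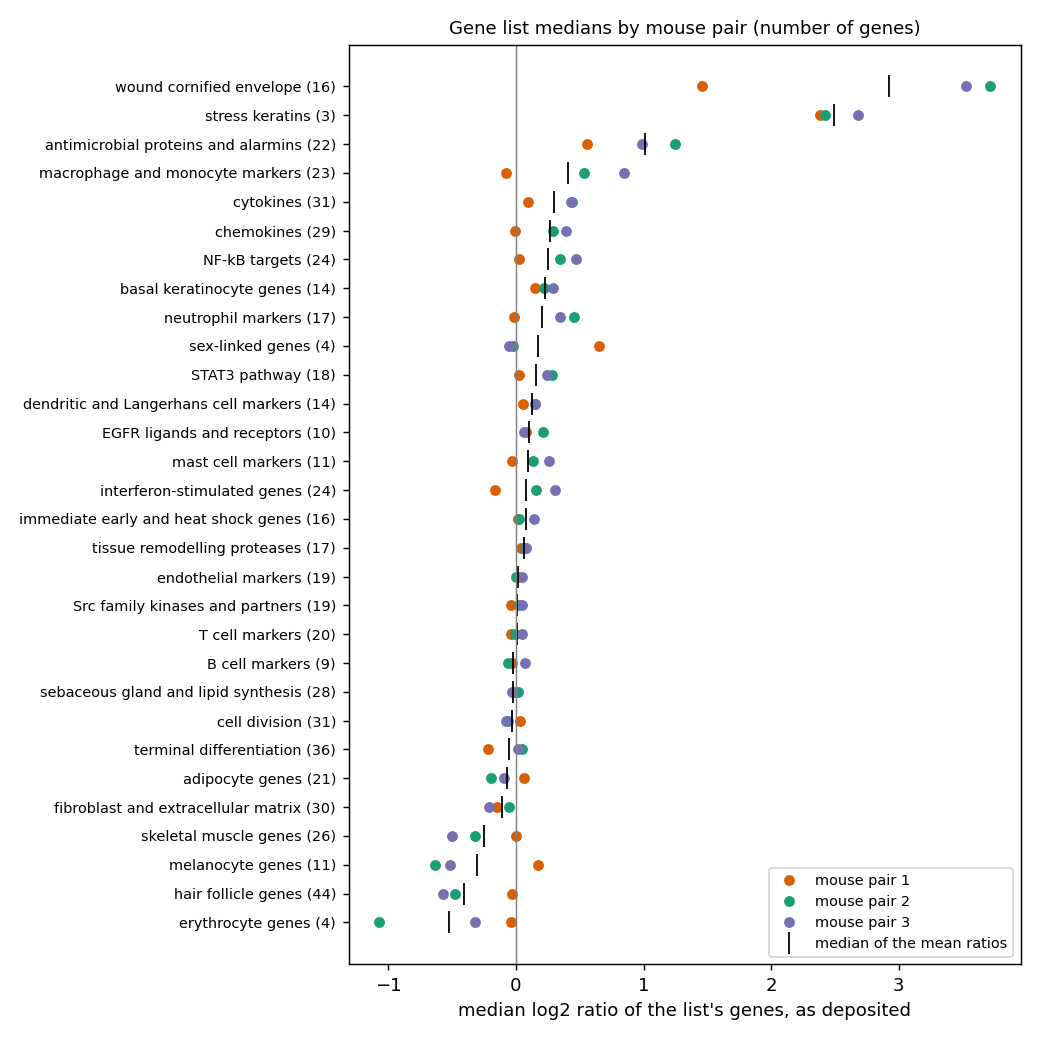
Median log2 ratio as deposited (horizontal axis) of each of 30 gene lists, with a point for each of 3 mouse pairs, a vertical mark for the median of the mean ratios, and the number of measured genes in parentheses. The wound cornified envelope lies at 2.93 and hair follicle genes at -0.41, and pair 1 lies closer to 0 than the mean of pairs 2 and 3 in 23 of 30 lists.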

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

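All alternatives were planned before the data were examined. The 4 called genes kept a positive ratio under every alternative: S100a9 ranged from 5.01 to 6.06, S100a8 from 4.12 to 5.10, Krt16 from 2.20 to 2.79 and Ccl20 from 2.08 to 2.22. Their calls ended without variance moderation (adjusted p = 0.446 for both alarmins and 0.535 for Krt16 and Ccl20), where 0 rows passed. Ccl20 also missed the threshold with quantile normalization (0.0613), and Ccl20 and Krt16 did without pair 2 (0.0776 and 0.127); over all settings adjusted p went from 1.92e-07 to 0.535. With the mouse pair as a replicate block 243 rows passed (138 positive, 105 negative), and with arrays as independent 319 (176 and 143); both include the 4 genes, and the block fit uses 6 arrays and 1 correlation for all rows. The block called 20 lists, adding immediate early and heat shock genes, and changed no other list call. Quantile normalization gave 72 rows (53 and 19), of which 3 were among the 4. The arrays with LynDN in Cy3 alone gave 54 (42 and 12) and those with LynDN in Cy5 alone 24 (12 and 12). With every probe as a row 1 negative probe passed. Leaving out 1 pair gave 2 to 1117 rows, 2 to 736 positive and 0 to 381 negative: 1117 without pair 1, 2 without pair 2 and 4 without pair 3. Of the 1117, 795 (71.2%) had the same sign in pair 1. Median and scale normalization and robust moderation gave 4 each, and the missing-value rule moved nothing since no value was missing. Of 29 lists, 14 to 21 were called under settings that kept the preset correlation, with 3 negative lists on the Cy3 arrays alone, and 0 lists, 0 positive and 0 negative, with an estimated correlation or with fry. The median of interferon-stimulated genes ranged from -0.016 to 0.23 when 1 pair was left out, and turned negative without pair 3 (-0.016, adjusted p = 0.790). Apart from the construction of each alternative the cause was not tested. For the 128 named genes, 1563 values under alternatives stayed on their side of the threshold, 8 of them uncalled with the opposite sign, 222 newly passed and 7 no longer passed. What signal over background limits could not be examined.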

Other observations

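The tests in this part were chosen after the results were seen, except the one on dye effects and the rearrangements of genotypes. Genes outside the fixed lists are given as values, picked after their values were seen from those with one sign on 6 arrays. None passed over all rows. On the positive side stood Gsta4, a glutathione transferase gene, at 3.07 ± 1.45 (SD, n = 3), the eosinophil-type ribonuclease genes Rnase2b and Ear6 at 2.85 ± 1.22 and 2.55 ± 0.88, which are close paralogs, and the lactoperoxidase gene Lpo at 2.10 ± 0.93. The glucose transporter genes Slc5a1 and Slc2a1 had 2.01 ± 0.86 and 1.23 ± 0.79. Uox and Urah, which encode successive enzymes of urate breakdown, had 1.82 ± 1.16 and 1.74 ± 0.76. The phospholipase genes Pla2g4e and Pla2g4d had 1.48 ± 0.91 and 1.37 ± 0.88, and the kallikrein genes Klk9 and Klk6 had 1.51 ± 1.20 and 1.48 ± 0.87. With the pair as a block, Gsta4, Rnase2b, Ear6, Lpo, Slc5a1 and Urah passed (adjusted p = 0.0273, 0.0244, 0.0103, 0.0267, 0.0256 and 0.0263), while Slc2a1, Uox, Klk9, Klk6 and both phospholipase genes did not.

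On the negative side stood Skint9, at -1.96 ± 1.01 (SD, n = 3), Wfdc21 at -1.75 ± 0.74 and Hal, the histidine ammonia-lyase gene of the cornified layer, at -1.56 ± 0.77. The epidermal lipoxygenase gene Alox12e had -0.72 ± 0.16 and Serpina12 had -0.69 ± 0.12. With the pair as a block all 5 passed (adjusted p = 0.0391 for Skint9, 0.0237 for Wfdc21, 0.0352 for Hal, 0.00886 for Alox12e and 0.00417 for Serpina12). In the order of protein-coding genes of GRCm38.p6, Lce1m, Flg and Rptn lie within 6 places of one another in the epidermal differentiation cluster, with Rptn 2 places from Flg. Rptn was positive and Flg and Lce1m negative in each pair: Rptn had 3.48, 5.78 and 5.58, Flg had -1.26, -2.51 and -2.91, and Lce1m had -1.68, -2.78 and -3.23 in pairs 1, 2 and 3. Tchh, the gene next to Rptn, had 0.58, 0.17 and -0.04 by pair. Beyond it, Tchhl1 had -0.10, -0.65 and -0.79, S100a11 had 0.01, 0.18 and -0.04, and S100a10 had -0.19, -0.30 and -0.11.

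The first pattern is the smaller ratios of pair 1, where 230 rows of at least 2-fold in the mean of pairs 2 and 3 kept a median fraction of 0.245, against 0.900 for pair 2 from rows picked in pair 3. Compression of all ratios alike on these arrays was set against macrophage and monocyte genes, a list picked after its pair medians were seen. Their median lay -0.28 from what that fraction predicts (spread of members 0.152), so these genes did not keep that fraction in pair 1. The list cannot decide on compression of all ratios, because of how it was picked and because its members vary together (estimated correlation 0.482). Weaker labelling or hybridisation remains open: pair 1 kept a median fraction of 0.256 of the dye effect of pairs 2 and 3, but pair 2 kept only 0.0659 of that of pair 3, a control added after the value was seen, so the dye effect cannot carry this test. The opposite sexes of its mice cannot be told apart from other properties of pair 1, since 1 pair alone was of that kind. A milder skin phenotype of LynDN mouse 1 stays open as well and was not tested.

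The second pattern is the negative ratios of hair follicle genes. Dilution of every resident cell type alike was set against endothelial markers, a list picked after its median was seen. The hair follicle median minus the endothelial median averaged -0.38 ± 0.30 (SD, n = 3), with -0.04, -0.48 and -0.62 by pair, so that the contrast rests on pairs 2 and 3. Some other resident lists were negative too, with medians of -0.30 for melanocyte, -0.25 for skeletal muscle and -0.11 for fibroblast and extracellular matrix genes. Sebaceous gland and adipocyte lists had -0.03 and -0.07. Basal keratinocyte genes, also resident, had a positive median of 0.23 (0.15, 0.22 and 0.29 by pair), with 12 of 14 members positive. The resident lists therefore did not all lie on one side. Reference lists picked after their medians were seen cannot decide on dilution. A different hair cycle stage of the mice in a pair may contribute: melanocyte genes, active in growing pigmented follicles, had the sign of the hair follicle genes in 2 of 3 pairs, which is too few to decide. A difference in the amount of hair follicle tissue between the genotypes, in either direction, stays open and was not tested.

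The third pattern is the sex-linked genes of pair 1. Mice of opposite sex are consistent with Eif2s3y at 3.50 in pair 1, with Kdm5d on the same side and Xist on the other on both arrays. A defect of single spots on one array is argued against by the 2 arrays of pair 1, which differed by 0.24 for Eif2s3y.

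Exchanging the genotypes within 1 mouse pair at a time gives 4 arrangements with the real one, too few for a share under 0.05. The real arrangement called 4 genes and the highest other 0, so 1 of 4 arrangements gave as many genes. For gene lists at the preset correlation, the real arrangement called 19 and the highest other 20, with genotypes exchanged in pair 1, so 2 of 4 arrangements gave as many lists. The other exchanges, in pair 2 or pair 3, called 2 and 1 lists.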
